A study of Arabidopsis thaliana with 12 samples.

How the data were processed

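Transcript levels were measured on 12 one-colour (Cy3) Agilent arrays, each hybridized with RNA of whole Arabidopsis thaliana seedlings grown for 5 days in the dark. The 4 genotypes were Col-0 (wild type), bes1-D, pif4pif5 and bes1-D;pif4pif5, with 3 independent biological samples each, as the series description states. Per the labels, seeds on medium with 1% sucrose were kept for 48 h at 4 °C, given 3 h of white light at 22 °C and then wrapped, and 0.5 ug of RNA per sample was labelled.

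The deposited scanner files hold, per spot, a processed signal whose unit is intensity: per the file headers, Agilent Feature Extraction subtracted the background and the spatial trend within each array and replaced low signals by surrogates, with no normalization between arrays. The same deposited files hold the mean raw signal and the median local background as intensity without normalization, and flags of another kind (0 or 1) for spots well above background, outlier spots and saturated spots. The file headers name Feature Extraction version 10.7.3.1 and the TAIR10 genome build, and the submitters' notes name version 9.1, so which of the versions applied to the value table is not known. The value table deposited by the authors is in log2 units. Its columns shared nearly the same distribution and each followed the log2 median signal of its own array (r across spots at least 0.99895). Its values thus appear to be quantile-normalized between arrays without background subtraction.

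Each array carried 45220 spots, of which 1417 were controls, and 43603 distinct probes. Of these probes, 36315 were named by 1 locus, 531 by several loci and 6757 by none. The locus came from a RefSeq accession for 34215 probes, from the gene name column for 1481 and from a symbol for 619. Between 68.96% and 78.94% of the spots of an array were well above background, no spot was saturated, and 44 to 968 spots per array were outliers and set to missing. The 75th percentile of the processed signal ranged from 3596.1 to 7473.0. Pearson's r across genes was 0.9434 to 0.9706 between arrays of a genotype and 0.8884 to 0.9669 between genotypes. Genes are not independent replicates, and the number of arrays limits the precision of every value.

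The log2 processed signal of each array was centred on its 75th percentile, and values below are on this scale. Probes well above background on at least 3 of the 12 arrays, with at least 2 values per genotype, were kept. The probe with the highest mean over all arrays stood for its gene, which gave 21479 genes with 1.28% of the values missing. The 12 arrays were fitted together with limma 3.58.1 in R 4.3.3 (prior degrees of freedom 5.14), with a mean per genotype and no further term. There were 6 comparisons: each mutant genotype against Col-0, bes1-D;pif4pif5 against pif4pif5 and against bes1-D, and the interaction, which is the effect of bes1-D in the pif4pif5 background minus its effect in the wild-type background. P values were two-sided and adjusted by Benjamini-Hochberg over all genes within a comparison, and a gene was called at an adjusted p under 0.05. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so none is reported per gene.

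For a gene not well above background on any array of 1 genotype, the fold change is given as a bound, printed as "at least" a fold. In the bound, each value of that genotype is raised to at least the lowest value seen among probes well above background on the same array, which ranged from -11.02 to -8.42. An interaction is given as a bound in the same way, where each such genotype enters it against its sign.

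Replicate numbers were the same as slides: each of the 3 slides held the 4 genotypes, slides 1 and 2 were scanned in a first session and slide 3 in a second, and Col-0 always had the first position. After removal of the genotype means, the 18 pairs of arrays with the same number correlated across genes at r = 0.113 to 0.640, and pairs with other numbers at -0.469 to 0.291. Only slide 3 stood apart, at 0.458 to 0.640, against 0.113 to 0.297 on slide 1 and 0.118 to 0.251 on slide 2. Pairs across slides 1 and 2 gave 0.079 to 0.291, so these slides showed no clear pairing of their own. 8 of the 12 arrays were closest on average to arrays with their own number. Counts from a fit with the slide as a block are therefore given beside those without it, and all gene calls made without the block were also made with it.

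The comparisons, the alternatives, the named genes and 22 gene lists were chosen before the data were examined. Genes named were BES1, PIF4 and PIF5, together with DWF4, CPD, BR6OX1, BR6OX2, IAA19, IAA29, PIL1 and HFR1, in every comparison. To these came the 5 called genes with the largest rise and the 5 with the largest fall in each comparison, for pairwise comparisons only where the arrays of the groups did not overlap. From each list came up to 4 called members with the smallest adjusted p, or the member with the smallest p where none was called. Every pairwise call among the named genes had the same sign on each slide that gave a value.

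The lists were BR (brassinosteroid) biosynthesis, BR inactivation, BR signalling, growth bHLH, PIF targets, light harvesting, photosystem and Rubisco, chlorophyll biosynthesis, carotenoid biosynthesis, light signalling, auxin response, cell wall, gibberellin, ethylene, flavonoid, glucosinolate, circadian clock, defence and cell cycle. There were also lists of root markers, of seed storage genes, chosen as marks of ungerminated seed, and of heat shock genes, chosen as marks of handling stress. Some genes stand in more than 1 list. Each list was tested with camera of limma, two-sided, at a preset correlation of 0.01 and adjusted over the 22 lists of a comparison, with missing values set to the genotype mean. Camera with an estimated correlation was the alternative, and its adjusted p is printed wherever it ended a call. Counts of members are given over all genes tested and adjusted over the list alone. They cover only listed genes that were among the genes tested. These were 8 of 16 for flavonoid, 8 of 15 for glucosinolate, 14 of 18 for defence and 17 of 18 for growth bHLH. The other lists were tested whole.

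For comparisons that share the Col-0 arrays, the correlation that the shared arrays alone produce was taken from 100 simulated data sets of unchanged genes. The number of shared calls per 1 Mb window of the genome was compared with 10000 random draws of as many tested genes. On simulated data in which 200 of 21479 genes were changed, the calls held 6.3% of the genes changed by 1 log2 unit, 57.3% of those changed by 2 and 93.9% of those changed by 3, with on average 6.2 false calls of 110.8. In the same runs an unchanged comparison gave 0 calls. In separate simulated data sets 20 of 20 shifted lists and 1 of 420 unshifted lists were called. Genes were simulated as independent of each other, so this does not show how the list test behaves with correlated genes.

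Alternatives were quantile normalization, normexp background correction (offset 50) of the raw signal, the authors' deposited values, no filter on dim probes, a filter on all arrays, the mean of all probes of a gene, the slide as a fixed or random block, the arrays of the compared groups only, a minimum 2-fold change, trended and robust variances, array weights, windows of other sizes, and leaving out each array and each slide. Chosen after seeing the data were normexp without aberrant background spots, the genes of chromosome 1 left out, and the slide as a fixed block together with an estimated correlation of the lists. Probes named by no locus or by several were left out of the gene tests, and the unnamed ones were tested on their own. The reference table of RefSeq names served for names only. Cross-matching of probes and sequence differences between the lines were not analysed here, as no genome sequence was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.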

Results

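The data set holds 12 arrays from dark-grown seedlings, 3 per genotype. BES1 is a transcription factor of the brassinosteroid pathway, and bes1-D is a dominant gain-of-function allele of it. PIF4 and PIF5 are bHLH transcription factors that interact with phytochromes and promote growth in the dark, and pif4pif5 lacks both by its label. By its title the series asks how far BES1 and PIF4 depend on each other in gene expression. Signals are log2 values relative to the array's 75th percentile, given as mean ± SD with n = 3 unless stated. Fold changes are log2 with the SE of the fit, and the number of arrays limits their precision.

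PIF5 (AT3G59060, probe on chromosome 3, 21828445 to 21828504, TAIR10) was at 0.56 ± 0.76 in Col-0 and 0.63 ± 0.12 in bes1-D. It was at -5.0 ± 0.53 in pif4pif5 and -6.23 ± 0.88 in the arrays labelled bes1-D;pif4pif5, where 2 of 3 arrays were above background. PIF4 (AT2G43010) was measured by a single probe (chromosome 2, 17888796 to 17888855). PIF4 stood at 1.38 ± 0.72 in Col-0, 0.88 ± 0.19 in bes1-D and -0.50 ± 0.69 in pif4pif5, but at 1.16 ± 0.28 in the arrays labelled bes1-D;pif4pif5. PIF4 therefore went against the label of these arrays: it differed from Col-0 by -0.23 (SE 0.41, adjusted p = 0.838) and from pif4pif5 by 1.66 (SE 0.41, adjusted p = 0.0333). The files do not give the insertion site, so whether this probe can report the mutation is not known. The arrays labelled bes1-D;pif4pif5 are called the double-labelled arrays below. The fall of PIF4 in pif4pif5 was -1.89 (adjusted p = 0.0488). It lost its call under 11 of the 12 single-array omissions. BES1 (AT1G19350) transcript was not called in any comparison, and its 3 probes differed in sign.

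**Figure D1:**
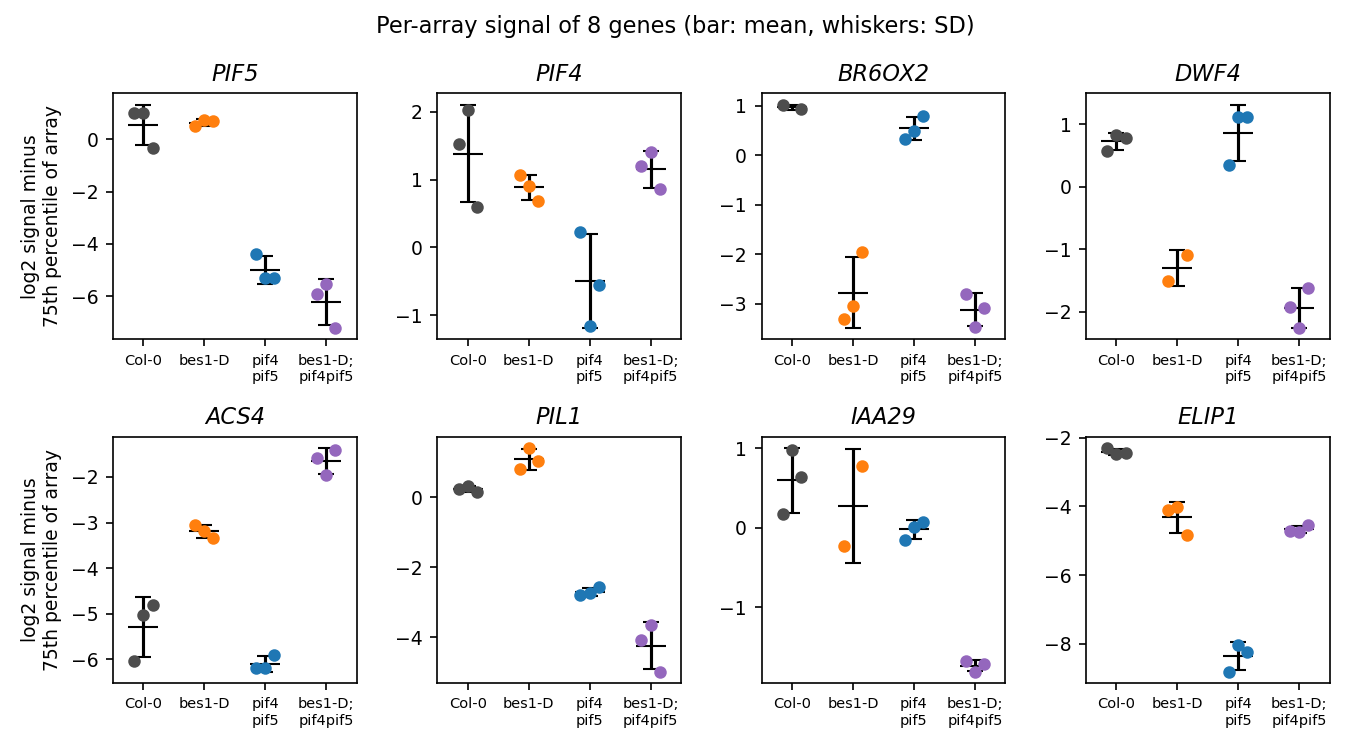
Log2 signal relative to the array's 75th percentile of 8 genes on each of the 12 arrays, by genotype; points are arrays, the bar is the mean and the whiskers are the SD (n = 3, or 2 where a spot was an outlier). PIF5 was low in both genotypes labelled pif4pif5, whereas PIF4 was low in pif4pif5 alone.

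The effect of bes1-D with PIF4 and PIF5 present was asked by bes1-D against Col-0. Among genes of brassinosteroid synthesis, 3 of 10 were called lower: BR6OX2, which makes the last steps of brassinolide synthesis, dropped from 0.98 ± 0.05 (n = 2) to -2.77 ± 0.72, a log2 change of -3.75 (SE 0.42, adjusted p = 0.000385). CYP90D1 (-3.88, SE 0.48) and DWF4 (-2.02, SE 0.36), both cytochrome P450 genes of the same pathway, fell as well, although DWF4 was not called without bes1-D replicate 2. Of the ethylene genes, 4 of 13 were called higher, among them the ACC synthases ACS8 (2.69, SE 0.54) and ACS4 (2.1, SE 0.34). The auxin-responsive SAUR9 rose by 3.11 (SE 0.39), from -0.74 ± 0.83 to 2.36 ± 0.15. Some transcripts of the photosynthetic apparatus fell: RBCS1B of the small Rubisco subunit (-3.09, SE 0.39), PSAH2 of photosystem I (-2.06, SE 0.42) and LHCB6 of the light-harvesting complex (-2.08, SE 0.33). Only 5 of 22 photosystem and Rubisco members and 1 of 17 light-harvesting members were called lower, and both list calls were lost with an estimated correlation (adjusted p = 0.0955 and 0.174).

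As lists, BR biosynthesis had 3 of 10 members lower and ethylene 4 of 13 higher (camera adjusted p = 6.78e-05 and 4.93e-05), and both calls held with an estimated correlation (adjusted p = 0.0202 for each). Adjusted over the list alone, 5 members of BR biosynthesis were lower and 1 higher, and 4 of ethylene were higher. Photosystem and Rubisco had 5 of 22 members lower (7 adjusted over the list alone; adjusted p = 4.93e-05), chlorophyll biosynthesis 1 of 17 (5 adjusted over the list alone; adjusted p = 6.78e-05) and light harvesting 1 of 17 (1 adjusted over the list alone; adjusted p = 0.0121). With an estimated correlation these calls were lost, at adjusted p = 0.0955, 0.124 and 0.174. With the slide as a block as well, photosystem and Rubisco was called (adjusted p = 0.0339) and the others were not (adjusted p = 0.0781 and 0.198). Auxin response had 4 of 28 members higher (6 adjusted over the list alone; adjusted p = 0.00103), a call lost at adjusted p = 0.174 with an estimated correlation. Carotenoid biosynthesis had 1 of 9 members lower, the phytoene synthase PSY at -2.35 (1 adjusted over the list alone; adjusted p = 0.0168), and light signalling had 4 of 27 lower (4 adjusted over the list alone; adjusted p = 0.00914). Their adjusted p with an estimated correlation was 0.0955 and 0.0801. The members of light signalling that fell were ELIP1 (-1.90), ELIP2 (-4.10), CGA1 (-2.11) and PIF7 (-1.98), so light-induced chloroplast genes as well as regulators. ELIP2 was not called without Col-0 replicate 3 or bes1-D replicate 1.

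Defence genes moved both ways in bes1-D. The jasmonate-induced VSP2 (-2.95, SE 0.34) and VSP1 (-2.15, SE 0.39) fell, and WRKY70 (2.13, SE 0.28), a regulator of salicylate responses, rose. The list as a whole, with 2 of 14 higher and 2 lower (2 and 2 adjusted over the list alone), was not called (adjusted p = 0.108). Glucosinolate genes were called higher, with 2 of 8 members including ESM1 at 2.44 (2 adjusted over the list alone; adjusted p = 0.0287), and lost the call with an estimated correlation (adjusted p = 0.124). GA2OX8, an enzyme that inactivates gibberellin precursors, rose by 3.66 (SE 0.45). Root markers were lower in 3 of 13 and higher in 1, LRX2 (6 and 1 adjusted over the list alone; adjusted p = 0.00854, and adjusted p = 0.0955 with an estimated correlation). Heat shock genes were higher in 1 of 10 (1 adjusted over the list alone, adjusted p = 0.00212, and adjusted p = 0.146 with an estimated correlation). At the preset correlation the lists chosen as marks of root share and of handling thus moved along with the groups above. Whether handling differed between the genotypes was not tested. Seed storage genes were not called (median -0.13, adjusted p = 0.677).

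The largest changes in bes1-D were of other kinds. AT5G54700 (at least 237-fold higher), CYP96A15 (6.99, SE 0.58), a cytochrome P450 of wax synthesis, AT4G18250 (at least 57.2-fold higher), AT3G21080 (5.805, SE 0.51) and AT1G58320 (5.735, SE 1.21) rose. AT1G58320 was not called without Col-0 replicate 1 or 3 or bes1-D replicate 1 or 2. AT1G58150 (at least 313-fold lower), AT1G29800 (at least 299-fold lower), AT1G29790 (-9.04, SE 0.76) and AT1G25211 (at least 166-fold lower) fell. LpxC2 fell by 9.71 with an SD of 4.15 among the bes1-D arrays, and as it belongs to a tandem family, which copies its probe reads was not tested. All 5 falls and 2 of the 5 rises, CYP96A15 and AT1G58320, were on chromosome 1, and the other rises on chromosomes 3, 4 and 5. In all, 1097 of 21479 genes were called, 607 higher and 490 lower, and 2159 (1137 and 1022) with the slide as a block. Arrays of the groups did not overlap for 21.1% of the genes, against 10% by chance. Single arrays mattered: without Col-0 replicate 1 or 2 there were 672 and 705 calls, and without bes1-D replicate 1 or 2 there were 615 and 650. Without Col-0 replicate 1 the balance turned, with 329 higher and 343 lower, and without Col-0 replicate 3 there were 456 higher and 296 lower. The authors' deposited values gave 576 calls, and 28 of the 48 calls among named genes stood without any single array.

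Comparing pif4pif5 with Col-0 asked for the effect of losing PIF4 and PIF5. PIL1, a bHLH gene induced by PIFs, fell by 2.94 (SE 0.34, adjusted p = 0.002), from 0.23 ± 0.09 to -2.70 ± 0.12. The early light-induced ELIP1 fell from -2.42 ± 0.09 to -8.36 ± 0.40, where 1 of 3 arrays was above background (-5.94, SE 0.31, adjusted p = 1.42e-06). Of the flavonoid genes, 2 of the 8 tested were called lower, with CHS, the chalcone synthase, at least 26.9-fold lower and F3H at -4.66 (SE 0.58). Of the heat shock genes 5 of 10 were called lower, such as HSP23.6 from -3.37 ± 0.35 to -6.53 ± 0.98 and HSP17.6A from -0.72 ± 0.57 to -3.66 ± 0.46. These genes were chosen as marks of handling stress, and whether handling or genotype lowered them was not tested. Among the largest rises were NAC036, a NAC-family gene (4.73, SE 0.59), and CRK40, a receptor-like kinase gene (4.29, SE 0.33).

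PIF targets had 2 of 16 members lower and 6 adjusted over the list alone, with all 16 values negative (median -0.77, camera adjusted p = 5.19e-07). Light harvesting had 3 of 17 members higher and 6 adjusted over the list alone, with all 17 values positive (median 0.85, adjusted p = 4.18e-09). Single calls in it depended on single arrays: LHCB1.1 (1.85) was not called without Col-0 replicate 1 or 3 or pif4pif5 replicate 1 or 3. Heat shock had 5 of 10 lower (7 adjusted over the list alone; adjusted p = 7.1e-09) and flavonoid 2 of 8 (3 adjusted over the list alone; adjusted p = 0.000158). Root markers had 1 of 13 lower (3 adjusted over the list alone; adjusted p = 0.00112). Light signalling had 4 of 27 lower and 1 higher (4 and 1 adjusted over the list alone; adjusted p = 0.0106), but the 4 were ELIP1, ELIP2 and the mutated PIF4 and PIF5, and the 1 was PIF7 (1.81). ELIP2 (-5.29) was not called without Col-0 replicate 3 or pif4pif5 replicate 1, and PIF7 under 7 of the 12 single-array omissions. These 6 calls held with an estimated correlation, at adjusted p = 0.0217, 0.0245, 0.0282, 0.0245, 0.0403 and 0.0403 in this order. With the slide as a block and an estimated correlation all 6 were lost, at adjusted p = 0.0571, 0.0571, 0.0702, 0.0571, 0.0753 and 0.0753.

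Other lists were called in pif4pif5 at the preset correlation only. Photosystem and Rubisco (median 0.37, adjusted p = 0.00237) and chlorophyll biosynthesis (median 0.50, adjusted p = 0.0238) were shifted higher with 0 called members and 0 adjusted over the list alone. Their adjusted p with an estimated correlation was 0.221 and 0.384. Auxin response (median -0.35, adjusted p = 0.0355, 0 called members and 0 adjusted over the list alone) was shifted lower and had an adjusted p of 0.413 with an estimated correlation. With the slide as a block its adjusted p was 0.0516. Cell wall (median -0.38, adjusted p = 0.0287, 0 called members and 1 lower adjusted over the list alone) and seed storage (median -0.56, adjusted p = 0.0355, 0 called members and 2 lower adjusted over the list alone) were shifted lower too, with adjusted p = 0.0698 and 0.493 with an estimated correlation. BR biosynthesis was not called (median -0.09, adjusted p = 0.643).

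In pif4pif5 against Col-0, 247 genes were called, 82 higher and 165 lower, and 820 (294 and 526) with the slide as a block. Non-overlapping arrays were seen for 19.4% of the genes, against 10% by chance. The count fell to 126, 109 and 101 without Col-0 replicates 1, 2 and 3, to 60 and 103 without pif4pif5 replicates 1 and 3, and to 161 without replicate 2 of the double-labelled arrays, which changes only the pooled spread. The higher calls among these were 25, 41 and 35, then 18 and 18, then 45, and the lower calls 101, 68 and 66, then 42 and 85, then 116. Without pif4pif5 replicate 2 it was 206 and the balance turned, with 116 higher and 90 lower. It was 74 with the authors' deposited values and 2, both higher, with normexp correction as planned. The normexp model failed on replicate 1 of the double-labelled arrays, which had 2 spots with aberrant background. Without those spots the normexp counts were higher, as given with the processing alternatives below. Among named genes, 13 of the 27 calls stood without any single array.

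By the labels, the double-labelled arrays against Col-0 asked for the effect of the combined genotype, although PIF4 was not called lower in them. PIL1 stood at -4.24 ± 0.67, a change of -4.47 (SE 0.34, adjusted p = 6.34e-06), and the PIF-induced genes IAA29 (-2.33, SE 0.34) and HFR1 (-2.01, SE 0.32) fell. CYP90D1 (-4.52, SE 0.48), BR6OX2 (-4.09, SE 0.42) and DWF4 (-2.66, SE 0.32) of brassinosteroid synthesis fell. ACS4 rose by 3.64 (SE 0.34) and WRKY70 by 2.89 (SE 0.28), while VSP2 fell by 4.42 (SE 0.34). Of the root genes, the nitrate transporter gene NRT2;1 (-3.29, SE 0.62) and the root-hair gene COBL9 (-2.80, SE 0.46) fell. The seed storage genes CRU3 (-7.20, SE 1.51) and CRA1 (-6.12, SE 1.11) fell against Col-0 arrays that themselves spread widely: CRU3 was at -5.65 in Col-0 replicate 1 and at 1.53 and 2.4 in replicates 2 and 3.

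By lists, PIF targets had 7 of 16 members lower and 2 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.000119). BR biosynthesis had 4 of 10 lower (5 adjusted over the list alone; adjusted p = 6.45e-05), ethylene 5 of 13 higher (7 adjusted over the list alone; adjusted p = 0.000119), and root markers 9 of 13 lower and 1 higher (9 and 1 adjusted over the list alone; adjusted p = 9.01e-05). These 4 calls held with an estimated correlation at adjusted p = 0.023, but not with the slide as a block as well (adjusted p = 0.116 for PIF targets and 0.0833 for the other lists). The higher PIF targets were ACS8 (2.17) and PRE5 (1.71). The calls of ACS8 were lost without Col-0 replicate 2 or replicate 2 or 3 of the double-labelled arrays, and that of PRE5 without Col-0 replicate 2. Light harvesting had 2 of 17 higher, LHCB1.1 at 2.18 among them (3 adjusted over the list alone; adjusted p = 0.000964), and seed storage 8 of 12 lower (10 adjusted over the list alone; adjusted p = 5.19e-07). Both lost the call with an estimated correlation, each at adjusted p = 0.124. Defence, with 4 of 14 higher and 2 lower (9 and 2 adjusted over the list alone), had adjusted p = 0.0551, and adjusted p = 0.039 with the slide as a block, a call lost with an estimated correlation (adjusted p = 0.286 with the block and 0.258 without it).

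Against Col-0, 1887 genes were called in the double-labelled arrays, 1067 higher and 820 lower, and 3140 (1664 and 1476) with the slide as a block. Groups did not overlap for 24.8% of the genes, against 10% by chance. Leaving out any single array moved this count by less than 1.5 times. The authors' deposited values gave 1195 calls. Normexp correction, whose model failed on replicate 1 of the double-labelled arrays, gave 525 higher and 89 lower. Among named genes, 39 of the 59 calls stood without any single array.

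By the labels, the effect of bes1-D in the pif4pif5 background was asked by the double-labelled arrays against pif4pif5, although PIF4 too was 1.66 higher in them. Of the genes of brassinosteroid synthesis, 4 of 10 were called lower, among them BR6OX2 by 3.66 (SE 0.37), from 0.55 ± 0.24 to -3.12 ± 0.33, CYP90D1 by 3.44 (SE 0.48) and DWF4 by 2.80 (SE 0.32). ACS4 (4.46, SE 0.34) and ACS5 (3.63, SE 0.45) rose, as did the auxin-conjugating GH3.1 (3.64, SE 0.53) and SAUR9 (2.92, SE 0.39). The heat shock genes HSP23.6 (3.70, SE 0.48) and HSP17.6II (2.96, SE 0.34) rose, and ELIP1 rose by 3.69 (SE 0.31). Whether handling or bes1-D raised the heat shock genes was not tested. IAA29 fell by 1.72 (SE 0.34). CYP78A10, a cytochrome P450 gene, was at least 543-fold higher.

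BR biosynthesis had 4 of 10 members lower (5 adjusted over the list alone; camera adjusted p = 2.85e-05), heat shock 6 of 10 higher (9 adjusted over the list alone; adjusted p = 4.1e-10) and ethylene 3 of 13 higher (3 adjusted over the list alone; adjusted p = 0.0025). These calls held with an estimated correlation, at adjusted p = 0.026, 0.0355 and 0.0478, and were lost with the slide as a block as well (adjusted p = 0.0826, 0.0888 and 0.11). Auxin response had 5 of 28 higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.000671, and adjusted p = 0.288 with an estimated correlation). Root markers had 4 of 13 lower and 1 higher (8 and 3 adjusted over the list alone; adjusted p = 0.0354, and adjusted p = 0.276 with an estimated correlation). Seed storage had 2 of 12 lower (3 adjusted over the list alone; adjusted p = 3.44e-05), and chlorophyll biosynthesis was shifted lower with 0 members called and 0 adjusted over the list alone (median -0.42, adjusted p = 0.034). With an estimated correlation these had adjusted p = 0.288 and 0.384. Defence had 3 of 14 higher and 2 lower (6 and 3 adjusted over the list alone; adjusted p = 0.0825, and 0.048 with the slide as a block), a call lost with an estimated correlation (adjusted p = 0.328 with the block and 0.371 without it). PIF targets, with 2 of 16 higher and 2 lower (4 and 2 adjusted over the list alone), were not called (median -0.39, adjusted p = 0.33). The lower ones were IAA29 and PIL1 (-1.53), and PIL1 was not called without pif4pif5 replicate 2 or 3 or replicate 3 of the double-labelled arrays.

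In this comparison 1212 genes were called, 799 higher and 413 lower, and 2125 (1348 and 777) with the slide as a block. The groups did not overlap for 23.2% of the genes, against 10% by chance. Without pif4pif5 replicate 2 or 3 there were 606 and 759 calls, without its replicate 1 there were 710 higher and 268 lower, and without replicate 2 or 3 of the double-labelled arrays 788 and 749. The authors' deposited values gave 564 calls. Normexp correction, whose model failed on replicate 1 of the double-labelled arrays, gave 279 higher and 32 lower. Among named genes, 34 of the 48 calls stood without any single array.

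By the labels, bes1-D was thus compared in both backgrounds with no array in common, although PIF4 was also 1.66 higher in the double-labelled arrays than in pif4pif5. Of its 1097 and 1212 calls, 518 were shared with the same sign, 344 higher and 174 lower, where 22.6 and 9.4 are expected by chance, and 4 had opposite signs. Fold changes correlated across genes at Pearson's r = 0.619 and Spearman's rho = 0.445. Among the genes called in the wild-type background, the median ratio of the change in the pif4pif5 background to that in the wild-type background was 0.695. Among the genes called in the pif4pif5 background the reverse ratio was 0.668, so each effect looked smaller where the genes were chosen by the other. The shared count was 972 with the slide as a block and 222 with the authors' deposited values. It was 56 with normexp correction, whose model failed on replicate 1 of the double-labelled arrays. It was 325 without Col-0 replicate 1, 321 and 328 without bes1-D replicates 1 and 2, and 290 without pif4pif5 replicate 2.

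By the labels, the double-labelled arrays against bes1-D asked for the effect of losing PIF4 and PIF5 in the bes1-D background, but PIF4 was not lower in them (1.16 ± 0.28 against 0.88 ± 0.19). PIL1 fell by 5.33 (SE 0.34, adjusted p = 3.17e-06), from 1.09 ± 0.30 to -4.24 ± 0.67, and PIF5 was lower (-6.87, SE 0.48). The PIF-induced cell wall gene XTH15 went from 5.72 ± 0.12 to 3.73 ± 0.47 (-1.99, SE 0.31, adjusted p = 0.0134). LHCB1.1 rose by 2.74 (SE 0.37), to 5.24 ± 0.43, and LHCB6 by 2.08 (SE 0.33). Of the largest changes, ZW9 (-7.86, SE 0.46) and AT1G62610 (-6.68, SE 0.54) fell, AT1G63880 fell from -2.14 ± 0.59 to a signal that was not above background on any of the 3 arrays, and AT1G63870 (3.68, SE 0.40), like them on chromosome 1, rose. XTH15 was not called without bes1-D replicate 1 or 3 or replicate 2 or 3 of the double-labelled arrays. LHCB1.1 was not called without bes1-D replicate 2, and LHCB6 without bes1-D replicate 2 or replicate 1 or 2 of the double-labelled arrays.

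PIF targets were lower in 4 of 16 members and in 9 adjusted over the list alone, with all 16 values negative (median -1.40, camera adjusted p = 1.78e-14). Light harvesting was higher in 4 of 17 members and in 10 adjusted over the list alone (median 1.06, adjusted p = 1.4e-14). Photosystem and Rubisco was higher in 2 of 22 members and in 10 adjusted over the list alone (median 0.99, adjusted p = 2.52e-14). These calls held with an estimated correlation, at adjusted p = 0.00156, 0.00667 and 0.0125. Chlorophyll biosynthesis was shifted higher with 0 members called and 2 adjusted over the list alone (adjusted p = 6.51e-07). Root markers were shifted lower with 0 called and 1 adjusted over the list alone (adjusted p = 0.00457), and seed storage with 3 of 12 lower and 9 adjusted over the list alone (adjusted p = 9.61e-12). With an estimated correlation these had adjusted p = 0.0786, 0.0786 and 0.0692.

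Against bes1-D, 104 genes were called, 40 higher and 64 lower, and 332 (164 and 168) with the slide as a block. Arrays did not overlap for 12.3% of the genes, against 10% by chance. The count was 61 without Col-0 replicate 2, 49, 49 and 62 without bes1-D replicates 1, 2 and 3, and 48, 46 and 51 without replicates 1, 2 and 3 of the double-labelled arrays. The higher calls moved most: in this order they were 18, then 13, 12 and 21, then 11, 9 and 9, and the lower calls 43, then 36, 37 and 41, then 37, 37 and 42. Without slide 2 there were 0 higher and 12 lower calls in limma (1096 genes at an unadjusted p under 0.05). It was 56 with the authors' deposited values and 0 with normexp correction in limma (1171 genes at an unadjusted p under 0.05). The normexp model failed on replicate 1 of the double-labelled arrays. Among named genes, 8 of the 23 calls stood without any single array.

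The effects of bes1-D and of pif4pif5 were compared against the same Col-0 arrays. They shared 71 calls of the same sign, 34 higher and 37 lower, and 13 of opposite sign. Independent comparisons would give 2.3, 3.8 and 6.5, but both subtract the same Col-0 arrays, so these are no chance level here. Examples of the shared falls were VSP2, ELIP1 and ELF4, a clock gene (-2.11 in bes1-D and -2.13 in pif4pif5). In pif4pif5 VSP2 (-1.69) was not called without any Col-0 array, without pif4pif5 replicate 1 or 3, or without replicate 2 of the double-labelled arrays. Fold changes correlated across genes at r = 0.416, where shared arrays alone gave 0.501 in simulation, and their covariance was 0.2385 against 0.1049 simulated. No gene was changed in the simulated sets, and changed genes alter r, so an r below 0.501 does not show that the effects were unlike. For the same reason the 0.05 calls that simulated sets shared on average give no chance level for the shared calls either. The shared count was 266 with the slide as a block and 32 with the authors' deposited values. Without Col-0 replicates 1, 2 and 3 it was 37, 46 and 35, without bes1-D replicate 1 it was 47, and without pif4pif5 replicates 1, 2 and 3 it was 19, 109 and 29. The comparisons of pif4pif5 with Col-0 and of the double-labelled arrays with bes1-D, in which PIF4 was not lower, had no array in common and shared 26 calls of the same sign, 11 higher and 15 lower, where 0.2 and 0.5 are expected, and 1 of opposite sign (r across genes 0.337).

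**Figure D2:**
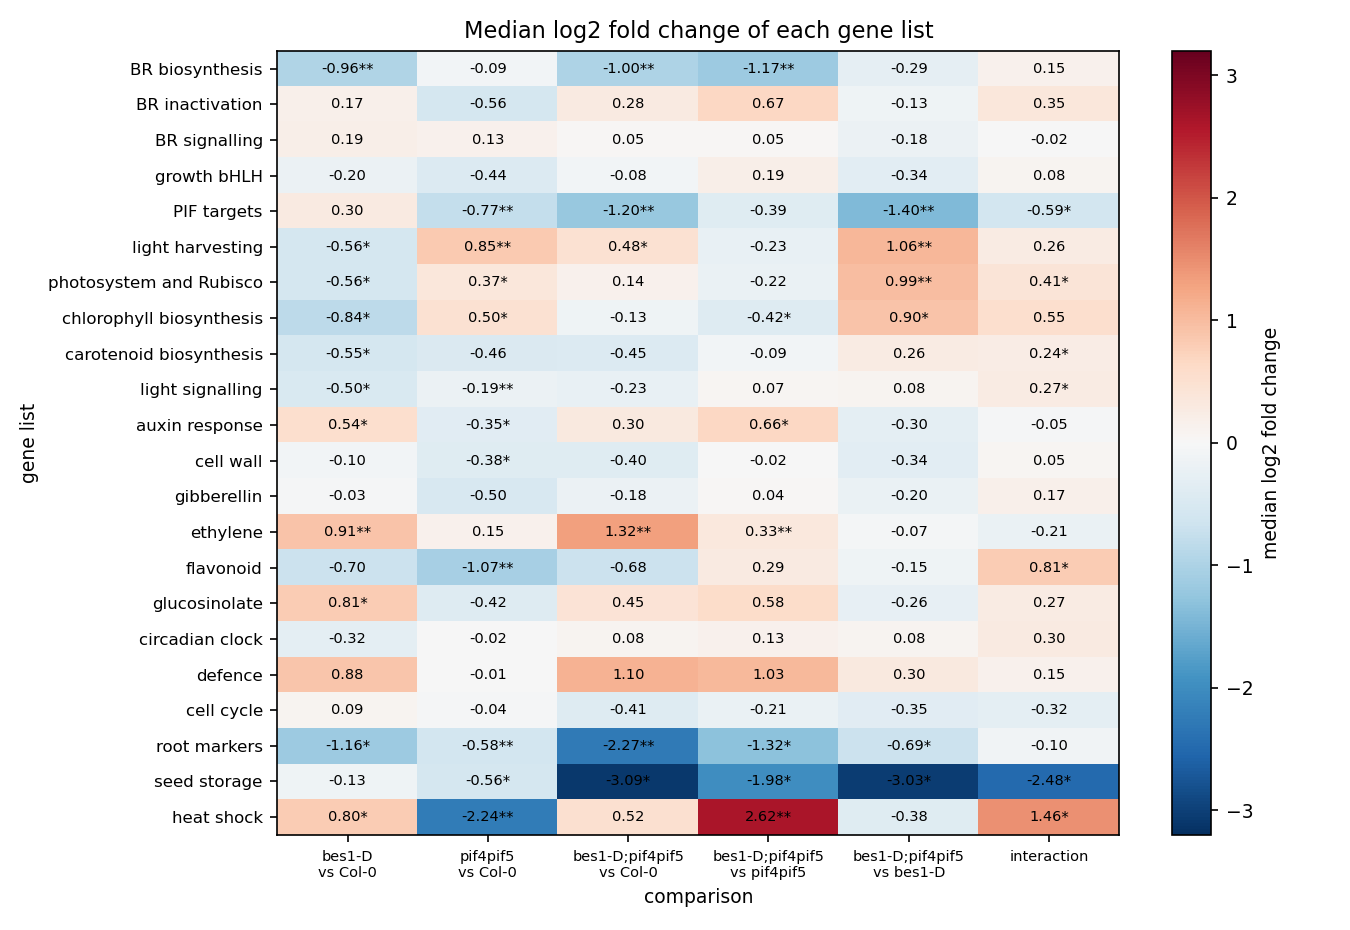
Median log2 fold change of the tested members of the 22 gene lists (vertical) in the 6 comparisons (horizontal); 1 star marks a camera adjusted p under 0.05 at the preset correlation and 2 stars one that also held with an estimated correlation, both without the slide as a block. PIF targets were lower and light harvesting higher in pif4pif5 against Col-0 and in the double-labelled arrays against bes1-D, and BR biosynthesis was lower in bes1-D against Col-0 and in the double-labelled arrays against pif4pif5.

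By the labels, the interaction asked whether the effect of bes1-D differed between the backgrounds. ELIP1 fell by 1.90 with bes1-D in the wild-type background and rose by 3.69 in pif4pif5, an interaction of 5.59 (SE 0.44, adjusted p = 5.68e-05). SDR1, a short-chain dehydrogenase gene, changed by -2.38 and 2.28 (interaction 4.67, SE 0.60, adjusted p = 0.0049). ELF4 fell by 2.11 with bes1-D in the wild-type background and changed by 0.71, not called, in pif4pif5 (interaction 2.82, adjusted p = 0.0217), a call lost under 10 of the 12 single-array omissions. Conversely, AT1G63860 (-8.28), ZW9 (-7.51) and AT1G61180 (-6.40) on chromosome 1 were low in the double-labelled arrays and changed by 1.23, -3.24 and 0.32 with bes1-D in the wild-type background. AT1G63880, also on chromosome 1, was not above background on any double-labelled array, so its interaction is a bound, -7.94 or lower, and it changed by 0.13 with bes1-D in the wild-type background. In all, 30 genes were called, 14 higher and 16 lower, and 77 (47 and 30) with the slide as a block. Of the 30, 16 lay on chromosome 1. Most of these were lower, whereas most calls on the other chromosomes were higher. The authors' deposited values gave 9 calls and normexp correction 0 in limma (924 genes at an unadjusted p under 0.05). The normexp model failed on replicate 1 of the double-labelled arrays. No single array moved the count by over 1.5 times. The higher calls alone fell to 8 without Col-0 replicate 2, bes1-D replicate 1 or pif4pif5 replicate 1, and to 9 without Col-0 replicate 3 or replicate 2 or 3 of the double-labelled arrays.

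At the preset correlation 7 lists were called in the interaction, and 0 with an estimated correlation (5 at an unadjusted p under 0.05). Heat shock genes were shifted higher (median 1.46, camera adjusted p = 1.98e-05), with 0 of 10 members called and 5 higher adjusted over the list alone. They were chosen as marks of handling, whose part in this shift was not tested. In the tested lists of brassinosteroid synthesis and ethylene the interaction was not called (adjusted p = 0.661 and 0.781).

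Calls also had a place on the genome. Of the 518 calls that bes1-D shared in both backgrounds, 172 (33.2%) were on chromosome 1, which held 26.4% of the genes tested. The fullest 1 Mb window, chromosome 1 from 8 to 9 Mb, held 21 of them among 208 genes tested, where the median of random draws was 12 (permutation p = 0.0002). The pif4pif5 calls, with 7 in their fullest window, showed no such gathering (permutation p = 0.788).

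**Figure D3:**
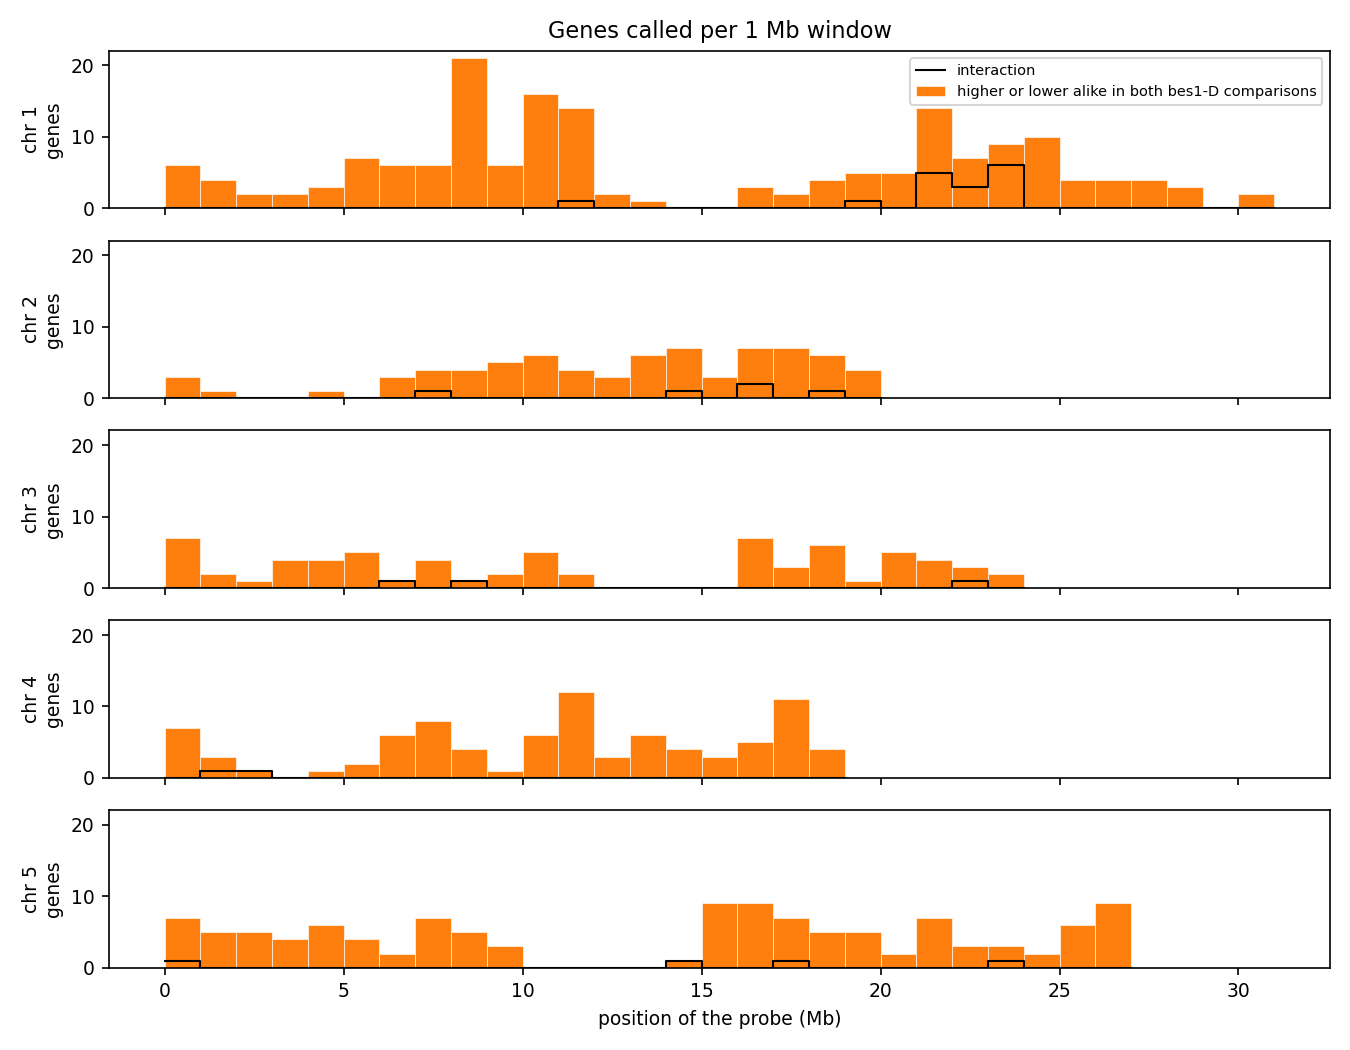
Number of called genes per 1 Mb window along the 5 chromosomes (positions in Mb); bars are calls of bes1-D shared by both backgrounds and the line is interaction calls. The fullest window of shared calls is on chromosome 1 from 8 to 9 Mb with 21 calls, and that of interaction calls on chromosome 1 from 23 to 24 Mb with 6.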

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

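Chosen only after the results were seen were the tests of neighbouring genes, of disagreeing probes, of the placement, chromosome share, slide and dim signals of the interaction calls, and of PIF4 and PIF5, while the placement of the shared bes1-D calls and the splits of the arrays were planned, and the splits within slides were added after the other results were seen but before their own.

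By the labels, the interaction of the limma fit compares the effect of bes1-D between the wild-type and the pif4pif5 background, although PIF4 was 1.66 higher in the double-labelled arrays than in pif4pif5. It was called for these named genes, which does not by itself show an effect of PIF4 and PIF5. The interaction was -7.51 for ZW9, -6.40 for AT1G61180 and -8.275 for AT1G63860, and it was 4.67 for SDR1, 4.37 for AT5G01015, 5.59 for ELIP1 and 2.82 for ELF4. Other genes were not above background on any array of a genotype, so their interactions are bounds. These were -7.936 or lower for AT1G63880 (the double-labelled arrays), -5.917 or lower for AT4G03950 (Col-0 and the double-labelled arrays), 5.754 or higher for AT1G62190 (pif4pif5) and 4.019 or higher for THI2.2 (bes1-D). The calls of AT1G62190 were lost without Col-0 replicate 2 or bes1-D replicate 1, and those of THI2.2 and ELF4 under 9 and 10 of the 12 single-array omissions.

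Among the gene lists, the interaction was called at the preset correlation, and not with an estimated one, for 7 lists. PIF targets had a median of -0.593 (adjusted p = 0.0286, and adjusted p = 0.164 with an estimated correlation). The photosystem and Rubisco list had a median of 0.408 (adjusted p = 0.00275, estimated 0.258) and carotenoid biosynthesis one of 0.236 (adjusted p = 0.0443, estimated 0.164). For light signalling the median was 0.265 (adjusted p = 0.00809, estimated 0.109) and for flavonoid 0.808 (adjusted p = 0.00354, estimated 0.109). Seed storage stood at -2.48 (adjusted p = 0.000968, estimated 0.311) and heat shock at 1.46 (adjusted p = 1.98e-05, estimated 0.119). With the slide as a block, chlorophyll biosynthesis was called too (adjusted p = 0.0448 against 0.117 without the block), and not with an estimated correlation (adjusted p = 0.384 with the block and 0.556 without it).

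Probes named by no locus, which the gene tests left out, held calls as well: 23 of 3145 such probes were called in bes1-D against Col-0, 11 higher and 12 lower, where 1097 of 21479 genes (5.11%) were. In the other comparisons, in the order of the report, 10 such probes (8 higher and 2 lower), 67 (40 and 27), 45 (17 and 28), 12 (5 and 7) and 5 (2 and 3) were called.

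Each pairwise comparison of 3 against 3 arrays allows 10 splits, too few for a share under 0.05. In each of the 5, 1 of the 10 splits, the real one, gave as many calls as the real one. The real counts were 1097, 247, 1887, 1212 and 104, in the order in which the comparisons are reported above, and the highest of the other splits in limma gave 0, 1, 0, 1 and 0. Among the 4 splits that part all 3 pairs of a slide, the highest other count was 0.

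For the interaction, 3 of 100 random splits of the 12 arrays that ignored the slides gave at least the real 30 calls, the real split included, a share under 0.05. The highest other split gave 466 calls, many times the real count, which points to a structure of the samples: it kept the Col-0 arrays together and largely set the genotypes against each other. Another, with 235 calls, had all 4 arrays of slide 3 on the same side and so followed the second scan session. Of these 100 splits, 6 kept all 4 groups on each slide, the real one included, and the highest other of them gave 20. Among 100 splits drawn to keep all 4 groups on each slide, 5 gave at least 30 calls, a share at which chance cannot be excluded. With the slide as a block 4 of them gave at least the real 77, a share under 0.05. The highest other of them gave 1791 calls (2412 with the block), which again points to a structure of the samples, as it set all Col-0 and pif4pif5 arrays against all arrays with bes1-D. Others, with 177 and 68 calls (296 and 66 with the block), set all Col-0 and bes1-D arrays against all pif4pif5 and double-labelled arrays. Such splits hold genotype effects, so none of these shares decides whether chance gave the interaction calls.

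The 518 calls that bes1-D shared in both backgrounds gathered on chromosome 1, and by count the fullest window, from 8 to 9 Mb, held 21. By share of the genes tested, the window from 21 to 22 Mb was fuller (10.85% against 10.1%). Random draws of single genes rarely reached the count of 21 (10000 draws, permutation p = 0.0002). These draws treat neighbouring genes as independent, so chance placement of groups of neighbours is not excluded. Near-identical neighbouring genes that cross-match remain open: with 1 call per 50 kb the fullest window held 12 against a median of 10 (permutation p = 0.0547), although such thinning also drops neighbours that are linked for other reasons. A stretch from another accession that stayed linked to the bes1-D allele may account for it too, and a disagreeing probe was seen in 3 of 14 genes with several probes (21.4%) inside the fullest windows and in 7 of 75 (9.3%) elsewhere (Fisher's exact test, two-sided p = 0.189), too few genes to decide. These windows of chromosome 1 start at 8, 10, 11 and 21 Mb, so they do not form 1 unbroken stretch, and their distance from BES1 was not examined. An effect of BES1 on neighbouring genes was not tested.

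The interaction calls gathered on chromosome 1 as well, with 6 from 23 to 24 Mb. Random draws of single genes rarely reached this count (permutation p = 0.0002), but they too treat neighbouring genes as independent. The calls as a set were not spread evenly: 16 of 30 were on chromosome 1, where 7.9 are expected (exact hypergeometric p = 0.00152). This test counts neighbouring genes as independent. A dependence on PIF4 and PIF5 spread over the genome beside a local group would give the same, so it is not decided. The other calls lay on chromosomes 2, 3, 4 and 5 (5, 3, 2 and 4). Each slide held the 4 genotypes, so a difference that all arrays of a slide or session share cancels from the interaction where no value is missing. Effects that differ among the arrays of a slide were not decided. All 16 stayed called with the slide as a block, but the block ended no gene call in any comparison, so this outcome was fixed. A stretch of chromosome 1 that differs between the lines may be the source, but the share of these calls not above background on any double-labelled array, 2 of 16 on chromosome 1 (12.5%) against 1 of 14 elsewhere (7.1%), did not decide (Fisher's exact test, two-sided p = 1). In the double-labelled arrays against bes1-D, 49 of 104 calls were on chromosome 1 (47.1%). The 1 Mb windows from 21 to 24 Mb held 5, 3 and 6 of the interaction calls. With 1 call per 50 kb the fullest window, from 21 to 22 Mb, held 5 against a median of 2 (permutation p = 0.0008). Calls of the double-labelled arrays against Col-0, pif4pif5 and bes1-D were also fullest from 23 to 24 Mb (44, 34 and 11). Those of bes1-D against Col-0 were fullest from 8 to 9 Mb (26).

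PIF4 was near the wild-type level in the double-labelled arrays. Mislabelled samples with intact PIF genes are argued against by PIF5, which differed from bes1-D by -6.87 (SE 0.48) in these arrays. A probe outside the disrupted part of PIF4 may report a transcript that is no longer functional, yet the same probe was 1.66 higher than in pif4pif5, so this explanation and a line that carries a functional PIF4 cannot be told apart without the insertion site.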

How the results depend on the processing

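Chosen only after the results were seen were normexp without aberrant background spots, the fits without the genes of chromosome 1, and the slide block together with an estimated correlation; all other alternatives were planned.

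Counts are given in the order bes1-D, pif4pif5 and the double-labelled arrays against Col-0, the double-labelled arrays against pif4pif5 and against bes1-D, and the interaction. Quantile normalization, the mean of all probes, and trended and robust variances kept all 6 counts within 1.5 times. A minimum 2-fold change did so too, but it could hardly move the counts. Nearly all calls already reached it, such as 1882 of 1887 in the double-labelled arrays against Col-0. Named genes were called in 216 cases, of which quantile normalization kept 190, the authors' deposited values 150 and no filter on dim probes 181. Of 48 calls of lists the authors' values kept 41 and an estimated correlation 18.

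Normexp correction as planned gave 139, 2, 614, 311, 0 and 0 calls, with 56 shared by bes1-D in both backgrounds, 1 shared by bes1-D and pif4pif5, and 3 lists called in the interaction. The median of all genes was then 0.20, 0.29, 0.24 and 0.34 in the last 4 comparisons, against -0.045, 0.004, -0.021 and 0.03 without it, and normexp kept 69 of the 216 named calls and turned 3: GA2OX1 (0.40, double-labelled against Col-0), and GA20OX3 (0.80) and SESA4 (0.09), both double-labelled against pif4pif5. Its model failed on replicate 1 of the double-labelled arrays, which has 2 spots with aberrant background (highest 178414), where the estimated mean was -1283.2 against 33.2 without those spots. Without them the counts were 705, 158, 1306, 776, 61 and 19 (11 of the last higher and 8 lower), with 307 shared by bes1-D in both backgrounds, and no named call turned.

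The authors' deposited values gave 576, 74, 1195, 564, 56 and 9 calls, with 222 and 32 shared; the cause was not tested. The slide as a fixed block gave 2159, 820, 3140, 2125, 332 and 77, with 972 and 266 shared, and as a random block 2089, 849, 3040, 2046, 344 and 84, with 962 and 268 shared. At the preset correlation the fixed block ended 1 call of a list (auxin response in pif4pif5) and added 3 (defence in the double-labelled arrays against Col-0 and against pif4pif5, and chlorophyll biosynthesis in the interaction), and changed no other. With this block and an estimated correlation 3, 0, 0, 0, 3 and 0 lists were called.

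Without a filter on dim probes pif4pif5 had 158 calls and the double-labelled arrays against bes1-D 68. With probes well above background on all arrays, and so fewer genes, the interaction had 11 calls and 3 lists, and bes1-D shared 341. With the arrays of the compared groups only, pif4pif5 had 95 calls, and 342 and 35 were shared. Array weights gave 454 calls in pif4pif5. Without the genes of chromosome 1 the double-labelled arrays against bes1-D had 40 calls, the interaction 10, and bes1-D shared 332. With an estimated correlation 2, 6, 4, 3, 3 and 0 lists were called. The placement of the shared calls had a permutation p of 0.0002 at each window size.

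Leaving out an array or a slide gave 190 to 1183, 15 to 236, 700 to 1917, 148 to 1249, 12 to 114 and 5 to 29 calls, 55 to 506 shared by bes1-D in both backgrounds, and 2 to 109 shared by bes1-D and pif4pif5. The lowest counts came without a slide, which leaves 2 arrays per group. Signal over background limits the fold changes of dim genes, given as bounds.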

Other observations

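The genes outside the rule for named genes were chosen only after their values were seen, and the tests in this part were planned.

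Away from chromosome 1, 14 genes were called in the interaction. YUC7, AT3G19480, MRN1 and NATA1 were chosen after their values were seen and were not examined under the alternatives. YUC7, a gene of auxin synthesis, was not above background on any bes1-D array, so it changed by -2.15 or lower with bes1-D in the wild-type background, and by 0.80 in pif4pif5 (interaction 2.944 or higher, adjusted p = 0.0479). AT3G19480, a gene of serine synthesis, changed by -2.88 and 0.53 (3.40, SE 0.47, adjusted p = 0.00866). MRN1, a triterpene synthase gene, changed by -4.44 and -0.93 (3.51, SE 0.54, adjusted p = 0.0173). NATA1, an acetyltransferase gene, was above background in the double-labelled arrays alone, so no size is given for its interaction (adjusted p = 0.0173). CRK40, named by the rule in pif4pif5, rose by 2.78 with bes1-D in the wild-type background and changed by -0.63 in pif4pif5 (-3.41, SE 0.47, adjusted p = 0.00866). The changes of YUC7, AT3G19480, MRN1 and CRK40 in the pif4pif5 background were not called.

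Lists that were not called in any comparison at the preset correlation without a block were BR inactivation, BR signalling, growth bHLH, gibberellin, circadian clock, defence and cell cycle. In bes1-D against Col-0 their medians were 0.17, 0.19, -0.20, -0.03, -0.32, 0.88 and 0.09, with adjusted p of 0.839, 0.677, 0.957, 0.957, 0.331, 0.108 and 0.957 in camera of limma. Single members were called, such as PRE5 of growth bHLH (1.79 in bes1-D and 2.18 in the double-labelled arrays against pif4pif5), a gene that promotes elongation. In bes1-D that call was lost without Col-0 replicate 1 or 2 or bes1-D replicate 2 or 3. IAA19, an auxin-induced gene, was not called in any comparison, at -1.73 in pif4pif5 (adjusted p = 0.129) and 1.78 in the double-labelled arrays against pif4pif5 (adjusted p = 0.0583). CPD was called in the double-labelled arrays against pif4pif5 alone (-1.61, adjusted p = 0.0409), and 8 of the 12 single-array omissions ended this call. Median, mean and test of a list differed in sign only where the list was not called: in bes1-D for BR inactivation, growth bHLH and gibberellin, in pif4pif5 for glucosinolate (median -0.42, mean 0.21) and defence, and in the double-labelled arrays for BR signalling against Col-0 and against pif4pif5. Against bes1-D this held for BR inactivation, light signalling, ethylene and defence, and in the interaction for BR biosynthesis, auxin response, glucosinolate and root markers.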
